A study of Mus musculus with 12 samples.

How the data were processed

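Genomic DNA of 12 mouse tumours was hybridised, 1 array per tumour, to Agilent 2-colour arrays for comparative genomic hybridisation. Per the labels' protocols, tumour DNA carried the red dye Cy5 and a common reference, DNA of normal kidney from C57BL/6 mice, carried the green dye Cy3. A positive log2 ratio therefore means more tumour DNA than reference DNA. The tumours were 4 renal cell carcinomas and 8 malignant lymphomas, from Mutyh knockout and wild-type C57BL/6 mice. Per the labels, the treated groups started with 20 male mice each, which received ferric nitrilotriacetate (Fe-NTA) by injection into the abdomen 5 times a week over 12 weeks. The dose was 3 mg iron per kg in the first week and 5 mg iron per kg in the following 11 weeks. The mice were killed at about 120 weeks, and DNA was extracted with the DNeasy kit.

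Per the file headers, the deposited intensity values are the processed signals of Agilent Feature Extraction 10.7.1.1 under its CGH protocol. They are background-subtracted, detrended and normalized between the dyes with the linear method. Per the file headers, Agilent's own log ratio column is the log10 of the processed red over green signal, and it was used as an alternative. The series-wide table holds, per a comparison with the deposited scanner values of each array, the log2 of the processed red over green signal without centring. Its column medians lay between -0.02 and 0.02, and its correlation with the scanner values was at least 0.99994 on each array. Per the file headers, probe positions are those of mouse build mm9. The RefSeq table used for names belongs to another build, GRCm38, so none of its coordinates are printed. Of 21138 gene names on the array, 15252 were symbols or older symbols of a RefSeq or Ensembl gene. The other names were kept as the array files give them, and 56418 probes lay in intervals with no gene name.

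Each array held 174305 spots that were not controls, for 170305 probes, of which 161460 lay on autosomes. The median distance between neighbouring autosomal probes was 10.84 kb, and the probes spanned 2407.8 Mb of autosomal sequence. Between 99.856% and 99.938% of spots were well above background in both colours, and Agilent's signal to noise ratio lay between 63.6 and 123.7. The number of arrays limits the precision of group comparisons. For each probe, the log2 of red over green processed signal was taken, spots that Feature Extraction marked as outliers were left out, and spots of the same probe were averaged. Each array was then centred on the median of its autosomal probes.

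Each chromosome was divided into segments by penalised least squares. The penalty was 10 times the logarithm of the number of probes times the noise variance, and the noise came from differences between neighbouring probes. A segment was called lost or gained when its mean was at least 0.25 from 0 over at least 5 probes. A call of at most 10 Mb was named focal, and a mean of at least 1 from 0 was named high-level. The segmentation was tested on simulated data. Inserted changes of 10 probes and log2 0.7 were found in 98.7% of cases, changes of 30 probes and log2 0.5 in 100.0%, and changes of 100 probes and log2 0.3 in 98.7%. Changes of 5 probes were found in at most 6.6% of cases, and 0 calls arose where nothing had been inserted.

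The choices of groups, tests, gene lists, rules for named genes and alternatives were made before the data were examined, except where the text says that a test or alternative was chosen after the data were seen. The percent of autosomal sequence in called segments and the number of called segments were compared with exact permutation tests on the difference in means, with Benjamini-Hochberg adjustment over these 6 tests. Carcinomas were compared with treated lymphomas, since all carcinomas came from treated mice. For the comparison of genotypes, labels were permuted within tumour type and the difference was the mean over both types, each weighted by the product of its numbers of knockouts and wild types over their sum. All permutation tests of group differences were two-sided. The value of a gene was the mean of its probes, and 661 probes were left out because their gene name also had probes on another chromosome. The 20310 autosomal genes with values on all arrays were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The model held tumour type, genotype and treatment as additive terms over all 12 tumours, and calls had an adjusted p under 0.05. In simulated data over the same 20310 genes, a difference of log2 0.4 was recovered for 58% of changed genes between tumour types, for 82% between genotypes and for 58% between treatments.

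The target gene Mutyh and the antigen receptor loci Igh, Igk, Igl, Tcra/Tcrd, Tcrb and Tcrg were compared with exact permutation tests. Recurrence was the highest number of tumours of a type with a call of the same sign at any autosomal probe. It was compared with 1000 random circular shifts of each tumour's calls, as a one-sided permutation test. For 9 gene lists, the number of pairs of gene and tumour with a call was compared with 10000 random circular shifts of the calls along the genes, one-sided. All tumours of a type were shifted together, so that calls shared between tumours stayed together, because separate shifts gave too many low p-values for random lists. Of 200 random lists of 20 genes, 10.5% had p under 0.05 in carcinomas with separate shifts and 3.5% with the shared shift. The shared shift was settled after the data were seen, and both results are given for the renal list. The lists covered renal carcinoma genes, lymphoma genes, base excision and oxidised base repair, and iron handling. Others covered the antioxidant response, cell cycle and p53, receptor kinases with their downstream kinases, mismatch and strand break repair, and large genes at common fragile sites. Of their 178 distinct members, 156 had a probe.

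Named genes followed 5 rules. They were Mutyh, list members in called segments with focal or high-level calls first and up to 25 per tumour type, and up to 10 higher and 10 lower genes per limma contrast with at least 2 probes and at most 3 within 2 Mb. Up to 5 genes per high-level segment and the receptor loci completed them. Alternatives covered other thresholds, penalties and minimum probe numbers, 1 Mb bins without segmentation, normexp background correction, Agilent's own log ratio, the series-wide table, centring on the mode, and only probes well above background. They also covered other summaries of genes, other model terms with slide as a block, and leaving out each tumour. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Correction for GC content with a genome sequence was not run, because no genome of the array's build was used here. Nothing was left out beyond control spots, spots marked as outliers and the probes named above.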

Results

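DNA copy number was measured in 12 tumours of mice with or without Mutyh, a DNA glycosylase that removes adenine mispaired with oxidised guanine. Some mice had received Fe-NTA, an iron chelate that causes oxidative damage to the proximal tubules of the kidney and renal carcinoma in rodents. The series holds 4 renal cell carcinomas and 8 malignant lymphomas. The carcinomas all came from treated mice, 3 of them knockouts and 1 a wild type. Among the lymphomas, 2 came from treated knockouts, 3 from treated wild types, 1 from an untreated knockout and 2 from untreated wild types. Each tumour is named by its genotype and animal number, as in carcinoma KO1080 or lymphoma WT1113. Each array read 161460 autosomal probes, with a signal to noise ratio of at least 63.6 in each colour. The arrays lay on 3 slides of 4 arrays each, and slide 1 held the 4 carcinomas. All positions are in mm9.

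The target gene came first, since it checks the genotype labels. The Mutyh probe on chromosome 4 at 116490496 to 116490555 read -2.73 ± 0.30 (SD, n = 6) in knockout tumours and -0.17 ± 0.30 (SD, n = 6) in wild-type tumours, as log2 ratios. It was lost in each of the 6 knockout tumours, where it lay between -3.15 and -2.42. The difference adjusted for tumour type was -2.38, with an exact permutation p of 0.00446, the smallest these 224 splits allow. Within slide 1 it read -2.99 ± 0.17 in the 3 knockouts and -0.74 in the wild type, within slide 2 it read -2.44 ± 0.02 and -0.06 ± 0.06 with 2 of each, and within slide 3 it read -2.56 in the knockout and -0.04 ± 0.16 in the 3 wild types. The other Mutyh probe, at 116480656 to 116480715, read -0.09 ± 0.28 in knockouts and -0.05 ± 0.38 in wild types, with an exact permutation p of 0.219. It carried no sign of the deletion and therefore checks no label. The mean of both probes differed by -1.11 between knockouts and wild types after adjustment for tumour type, with an exact permutation p of 0.00446.

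Knockout and wild-type tumours were compared to ask whether loss of Mutyh changes the amount or the place of copy number change. Among genes with at least 2 probes, members of the Skint family had the lowest ratios in the knockouts. These genes encode proteins of the immunoglobulin superfamily of skin and thymus epithelium. A transcript read by 1 probe, ENSMUST00000117091, was lower by -3.33 ± 0.11 (SE). Skint3 was lower by -3.94 ± 0.09 (SE, n = 6 against 6), Skint9 by -3.73 ± 0.11, Skint6 by -2.38 ± 0.06 and Skint4 by -2.25 ± 0.08, with limma adjusted p-values of at most 2.4e-09. Skint5 and Skint10 were lower by -0.94 ± 0.05 and -0.92 ± 0.06. Mutyh itself was lower by -1.11 ± 0.07, and Dmbx1, a homeobox gene at 115589287 to 115607473, was higher by 0.72 ± 0.08. In total 13 genes passed the test, 2 higher and 11 lower, against 1057 with an unadjusted p under 0.05. All but 1 lay on chromosome 4 between 107806320 and 116490555, around Mutyh. The exception, AK044741 on chromosome 1, rests on a single probe and was lower by -0.50 ± 0.07 with an adjusted p of 0.0137. At 85 probes, each knockout tumour lay at least 1 below each wild type after subtraction of the chromosome mean. All 85 were on chromosome 4 between 107816653 and 119519635, 82 of them from the first to the last of the 11 Skint genes on the array, and 0 were on other autosomes. Their mean was -3.11 ± 0.18 in knockouts and -0.05 ± 0.03 in wild types. Fitted without chromosome 4, limma called 0 genes, against 1005 with an unadjusted p under 0.05.

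**Figure D1:**
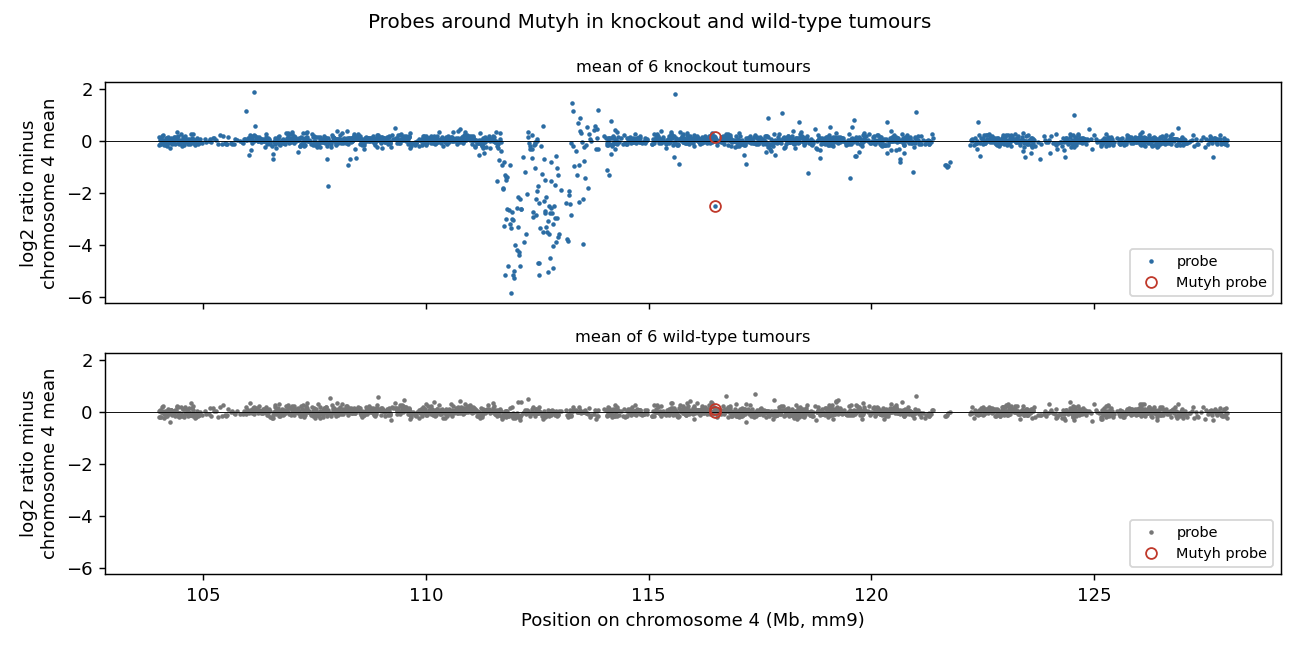
Mean log2 ratio of each probe, after subtraction of each tumour's chromosome 4 mean, against its position in Mb (mm9), for the 6 knockout tumours (top) and the 6 wild-type tumours (bottom), with both Mutyh probes circled. Of the 85 probes low in each knockout, 82 lie among the Skint genes, and 1 Mutyh probe is low in the knockouts while the other is near 0.

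Neither measure of the amount of change differed detectably between genotypes with arrays centred on the median. Called segments covered 10.6 ± 9.03% of autosomal sequence in the 3 knockout carcinomas and 21.1% in the wild-type carcinoma WT1179. Centred on the mode, the carcinomas no longer differed in this way, with 21.97 ± 12.25% in the knockouts and 21.13% in WT1179. With arrays centred on the median, called segments covered 0.856 ± 0.637% in the 3 knockout lymphomas and 5.05 ± 3.10% in the 5 wild-type lymphomas. The difference adjusted for tumour type was -6.01 percentage points, with an exact permutation p of 0.0670 and an adjusted p of 0.134. Within slide 2, the 2 knockout lymphomas had 0.512 ± 0.320% and the 2 wild types 7.48 ± 0.303%, and within slide 3 the knockout had 1.54% and the 3 wild types 3.44 ± 3.05%. The 2 wild types of slide 2, WT1113 and WT1114, had profiles that correlated at 0.743 over 1 Mb bins and may not be independent. The number of called segments differed by 0.381, with an exact permutation p of 0.969. That number includes the short losses around Mutyh, and without chromosome 4 the difference was -8.71 segments. Both values lean on WT1179, the only wild-type carcinoma, with 36 segments and 33 without chromosome 4. Knockout and wild-type lymphomas had means of 14.67 and 8.0 segments, and of 6.0 and 7.8 without chromosome 4. The difference turned its sign in 15 of 30 alternatives. With probes centred on their median over arrays it was -21.4 and passed, with an adjusted p of 0.0268, where the alternatives ranged from 0.0268 to 1.0.

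Carcinomas and lymphomas were compared to see which changes belong to the renal tumours that Fe-NTA induces. Among autosomes, chromosomes 4 and 12 differed most. The mean log2 ratio of chromosome 4 was -0.51 ± 0.20 (SD, n = 4) in carcinomas and -0.06 ± 0.04 (n = 5) in treated lymphomas, and that of chromosome 12 was -0.46 ± 0.24 and 0.00 ± 0.02. Both chromosomes were called lost over almost their whole length in carcinomas KO1080, KO1097 and WT1179. Carcinoma KO1134 was the shallowest of the 4 on both chromosomes, with a chromosome 4 mean of -0.26 and a chromosome 12 mean of -0.15. For each of both chromosomes the exact permutation p was 0.00794, the smallest these splits allow, and 0.0556 after adjustment over 21 chromosomes. Against all 8 lymphomas it was 0.00202 and 0.0212. Chromosome 18 had the same p of 0.00794 and adjusted p of 0.0556 against treated lymphomas, with means of only 0.03 ± 0.02 and -0.00 ± 0.01, and it lay between -0.01 and 0.01 in the carcinomas centred on the mode. These tests of whole chromosomes were chosen after the data were seen.

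**Figure D2:**
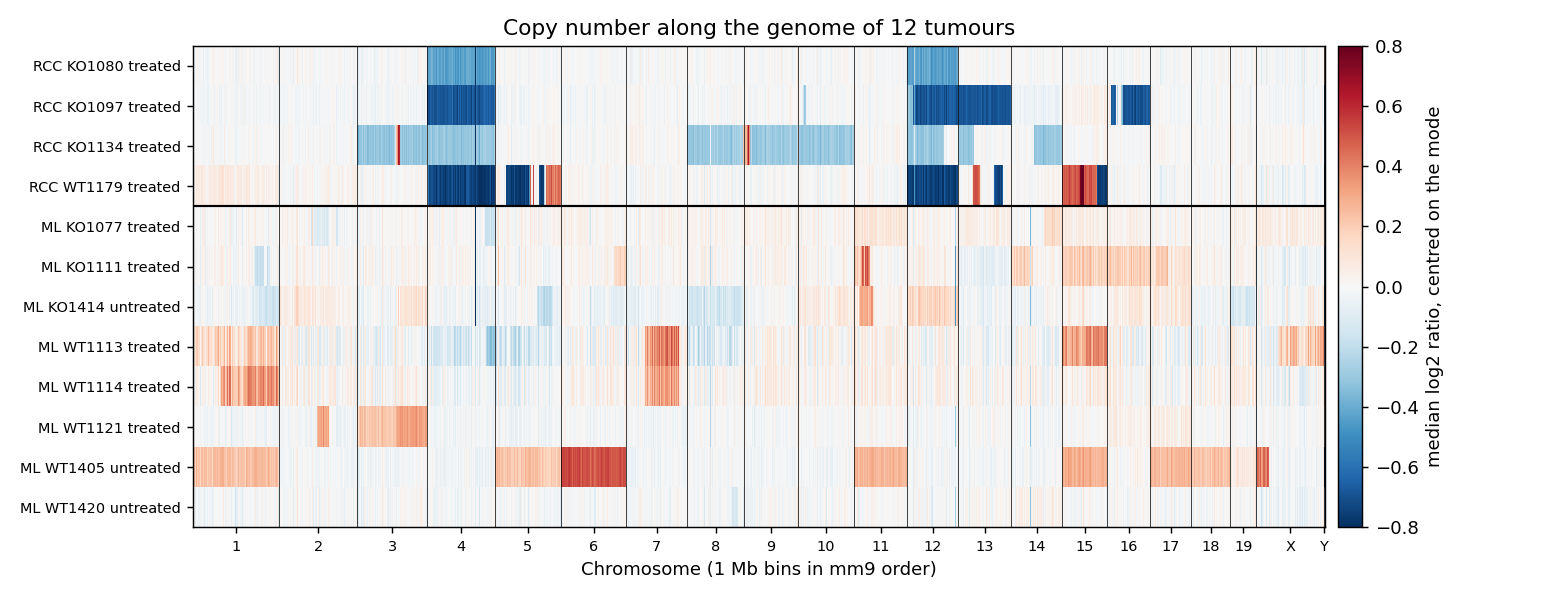
Median log2 ratio in 1 Mb bins, centred on the mode of each array, for 12 tumours (rows) along the chromosomes in mm9 order, with blue for loss, red for gain and a line between carcinomas (above) and lymphomas (below). Chromosomes 4 and 12 are blue in carcinomas, and the lymphomas show mainly gains.

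Genes on these chromosomes made up most of the difference between tumour types. limma called 2536 genes, 396 higher and 2140 lower in carcinomas, against 4834 with an unadjusted p under 0.05, and 85.8% of the lower genes lay on chromosomes 4 and 12. Cdkn2a, the locus of the cell cycle inhibitor p16 and of p19Arf, was lower by -0.44 ± 0.11 (SE, n = 4 against 8), with an adjusted p of 0.0120. It read -0.42 in KO1080, -0.64 in KO1097, -0.20 in KO1134 and -0.79 in WT1179. Hif1a, the hypoxia-inducible transcription factor, was lower by -0.73 ± 0.11, and Arid1a, a subunit of the SWI/SNF chromatin remodeller, by -0.50 ± 0.09. The genes with the lowest ratios and a symbol were Kif26a at -1.04 ± 0.11 and Cbll1 at -1.04 ± 0.09, both on chromosome 12, and Shmt1, a serine hydroxymethyltransferase on chromosome 11, at -0.97 ± 0.08. Chromosome 11 had 0 called segments in each of the 4 carcinomas, with means from 0.01 to 0.08. The Shmt1 value therefore rests on its own probes, with no called loss behind it. Others among the lowest were Snapc1 at -0.90 and Soat2 at -0.88. Among higher genes, Bfsp1 on chromosome 2 had 0.43 ± 0.07, and Zdhhc4, Arpc1a, Slc7a1, Afp and Tbx3, all on chromosome 5, had 0.43, 0.40, 0.38, 0.37 and 0.37. Chromosome 5 held 143 of the 396 higher genes, and among the carcinomas only WT1179 had called gains on this chromosome. The count of higher genes depended on the processing. It was 175 centred on the mode and 1 with segment means, where 2590 and 2095 genes were lower. Tumour type and slide 1 coincide for carcinomas, so no fit can separate tumour type from slide. With slide as a random block the count was 3271, at a fitted correlation within slides of -0.066, and this count does not speak against an effect of slide.

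The carcinomas tended to carry more change, but not beyond the spread between tumours. Called segments covered 13.2 ± 9.07% of autosomal sequence in carcinomas (SD, n = 4) and 4.02 ± 3.49% in treated lymphomas (n = 5). The difference of 9.20 percentage points had an exact permutation p of 0.0635 and an adjusted p of 0.134. Carcinomas had 24.5 called segments, between 14 and 36, and treated lymphomas 12.2, between 7 and 16, with the same p and adjusted p. These numbers include receptor loci, the chromosome 14 interval and the short losses around Mutyh in knockouts. Knockouts made up 3 of the 4 carcinomas and 2 of the 5 treated lymphomas. Outside these regions, carcinomas had between 4 and 35 called segments and treated lymphomas between 0 and 13. The number of segments is therefore not a measure of tumour change alone. In carcinomas 11.6 ± 8.22% was lost and 1.66 ± 2.66% gained, whereas in all 8 lymphomas 0.217 ± 0.214% was lost and 3.26 ± 3.14% gained. Centred on the mode instead of the median, the percentages differed by 17.1, with an adjusted p of 0.0476, where 25 alternatives ranged from 0.0476 to 0.333.

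**Figure D3:**
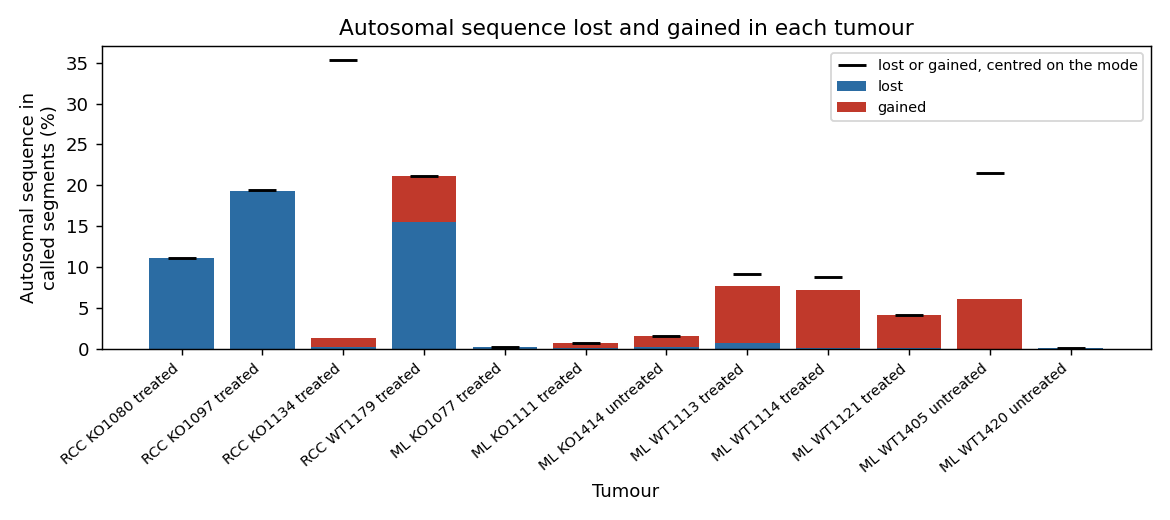
Percent of autosomal sequence in called segments that were lost (blue) or gained (red) in each tumour, with a black mark for the sum of both when arrays were centred on the mode. The bars range from 0.103% in lymphoma WT1420 to 21.1% in carcinoma WT1179. Centred on the mode, carcinoma KO1134 moves from 1.29% to 35.3% and lymphoma WT1405 from 6.09% to 21.5%.

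Carcinomas KO1097, KO1134 and WT1179 also had calls on other chromosomes, whereas those of KO1080 lay on chromosomes 4 and 12 and in an interval of chromosome 14 gained in most tumours. KO1097 lost chromosome 13 at -0.62 and most of chromosome 16, at -0.64 from 61004708 to 98280304. WT1179 gained chromosome 15 up to 81680598, with the highest level of 0.89 from 43218775 to 50738919, and lost the rest of it at -0.71. In WT1179, chromosome 13 was gained at 0.50 from 35805638 to 53298312 and lost from 84225869 to 102761300. KO1134 had focal gains on chromosome 3 at 94820951 to 98785519, with a mean of 0.72, and on chromosome 9 at 12474601 to 16251666, with a mean of 0.69. These held Hfe2, which encodes the iron regulator hemojuvelin, at 0.79, and Mre11a, a nuclease of double-strand break repair, at 0.68.

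Chromosome 5 of carcinoma WT1179 switched back and forth between loss, gain and no call. It held 12 called losses over 66.4 Mb with means from -0.81 to -0.66, and 9 called gains over 38.3 Mb with means from 0.42 to 0.58. There were 26 changes of state along this chromosome, and the next highest number in any tumour was 7, on chromosome 16 of KO1097. Chek2, a checkpoint kinase, read -0.80 and Ung, the uracil DNA glycosylase, read -0.80 in the lost parts.

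**Figure D4:**
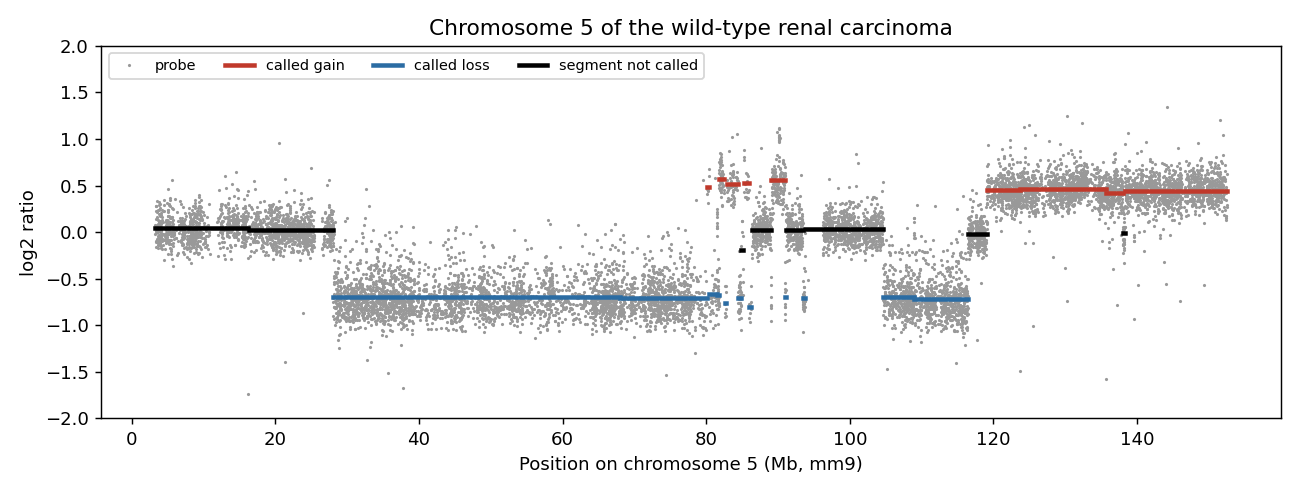
Log2 ratio of each probe of carcinoma WT1179 against its position on chromosome 5 in Mb (mm9), with called gains in red, called losses in blue and segments not called in black. The called segments lie at few levels, losses between -0.81 and -0.66 and gains between 0.42 and 0.58.

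Treated and untreated lymphomas were compared to see what Fe-NTA adds to lymphomas that also arise without it. The treated lymphoma WT1121 gained chromosome 2 from 90585221 to 117183028 at 0.32 and chromosome 3 from 91249522 to its end at 0.32. Treated lymphomas WT1113 and WT1114 both gained chromosome 7 from 58075000 to 133995167, with means of 0.39 and 0.30, and WT1113 also gained most of chromosome 15. KO1111, treated, gained chromosome 11 from 20612335 to 24595414 at 0.49 and from 27956982 to 38580041 at 0.46. Both intervals lay inside a gain of the untreated KO1414 from 15233901 to 45091892. The untreated WT1405 gained all of chromosome 6, with means from 0.42 to 0.45. In KO1077 and WT1420, called changes lay only at the antigen receptor loci, in the chromosome 14 interval gained in most tumours, and, for KO1077, around Mutyh.

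Between treated and untreated lymphomas, neither measure of the amount of change passed its test. Called segments covered 4.02 ± 3.49% in 5 treated and 2.58 ± 3.12% in 3 untreated lymphomas, a difference of 1.44 percentage points with an exact permutation p of 0.571 and an adjusted p of 0.686. Its sign depended on the processing, with -3.11 centred on the mode, -4.09 at a threshold of 0.15 and -1.67 at a threshold of 0.4. The number of segments was 12.2 ± 4.76 and 7.67 ± 4.73, with an exact permutation p of 0.161 and an adjusted p of 0.241. limma called 0 genes between treatments, against 2329 with an unadjusted p under 0.05. Within slide 3, the only slide with both arms, the treated WT1121 had 4.12% and the 3 untreated lymphomas 2.58 ± 3.12%. Without WT1121, when treatment and slide coincide among lymphomas, 460 genes were called.

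The antigen receptor loci were compared because lymphocytes delete parts of them when they assemble their receptors, whereas the kidney reference keeps them. The locus Tcra/Tcrd on chromosome 14 read -0.20 ± 0.08 (SD, n = 8) in lymphomas and -0.00 ± 0.03 (n = 4) in carcinomas, with a two-sided exact permutation p of 0.00404 and an adjusted p of 0.0242 over 6 loci. Focal losses were called at Igh in 7 of 8 lymphomas, at Igk in 5, at Tcra/Tcrd in 5 and at Tcrb in 4, and in 0 of the 4 carcinomas at each of them. The lowest Igh loss was that of WT1121, with a mean of -1.06, and the shallowest was that of KO1077, at -0.30. Both the B cell loci Igh and Igk and the T cell locus Tcra/Tcrd carried focal losses in KO1077, KO1414, WT1114 and WT1121. Igh did not pass the test, with lymphomas at -0.23 ± 0.10 and carcinomas at -0.39 ± 0.34 and an adjusted p of 0.271, and Igh lies on chromosome 12, which was called lost in 3 carcinomas. Igk, Igl, Tcrb and Tcrg had adjusted p-values of 0.258, 0.176, 0.258 and 0.499.

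With each tumour's chromosome mean subtracted, a step chosen after the data were seen, 5 of the 6 loci differed. Igh was then lower in lymphomas by -0.31, Igk by -0.20, Tcra/Tcrd by -0.21 and Tcrb by -0.18, with adjusted p-values of 0.00606, 0.0121, 0.00808 and 0.00606 from exact permutation tests. Igl was higher by 0.07, with an adjusted p of 0.0461, and Tcrg was lower by -0.07, with an adjusted p of 0.117. After the subtraction Igl read -0.156 in carcinoma KO1097, against -0.046, -0.01 and -0.065 in the other carcinomas. In KO1097, 76.2% of chromosome 16 was called lost, Igl included, so the chromosome mean removes that loss only in part. Without the subtraction, Tcra/Tcrd did not pass centred on the mode or when lymphoma WT1121 or WT1420 was left out, and 4 loci passed when WT1405 was left out.

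**Figure D5:**
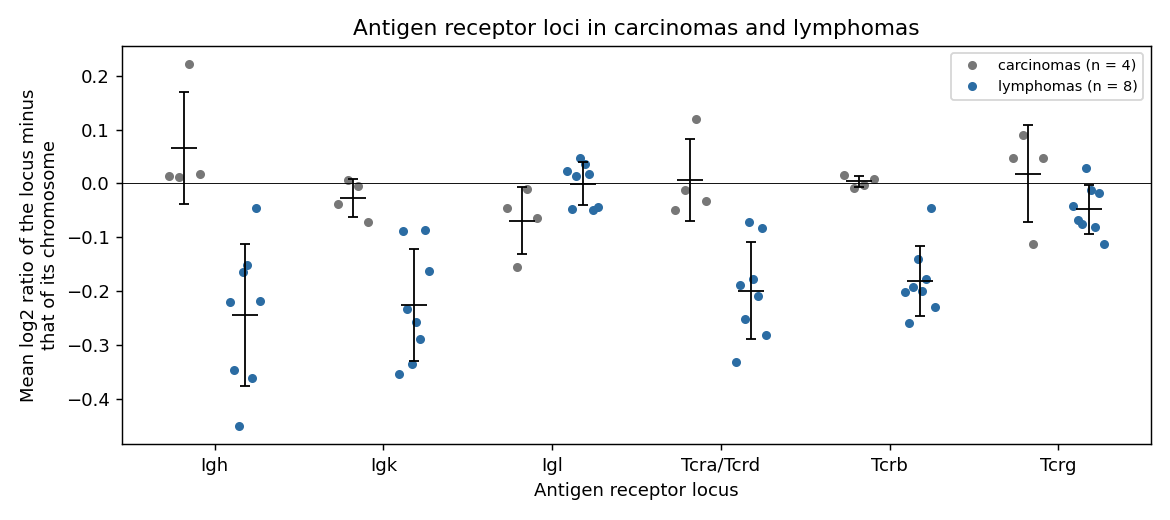
Mean log2 ratio of 6 antigen receptor loci minus the mean of their chromosome, for 4 carcinomas (grey) and 8 lymphomas (blue), with the mean and SD of each group in black. Igh, Igk, Tcra/Tcrd and Tcrb lie lower in lymphomas, by -0.31, -0.20, -0.21 and -0.18.

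Recurrent regions were sought to find sequence that tumours of a type lost or gained together. In carcinomas, losses on chromosome 4 reached all 4 tumours from 107837035 to 111696213 and from 119535132 to 121767386, on both sides of Mutyh. In KO1134, the calls from 107837035 to 111696213 and from 118594472 to 121395021 had means of -0.253 and -0.265, just past the threshold of 0.25. The median over the whole chromosome 4 of KO1134 was -0.232. Losses of chromosome 12 reached 3 tumours over its whole length. The highest number of 4 had a one-sided permutation p of 0.00300 against random shifts. It did not pass centred on the mode or at a threshold of 0.15, both with p of 0.0779, with probes centred on their median over arrays, where p was 0.195, or without carcinoma KO1134, where p was 0.209. In lymphomas, the highest number was 7, at Igh, with a one-sided permutation p of 0.000999, the smallest the shifts allow. An interval on chromosome 14 from 69876584 to 70090608 was gained in 10 of the 12 tumours. All 4 carcinomas were among them, so their highest number of 4 does not rest on chromosome 4 alone. Without the receptor loci, this interval and the sequence around Mutyh, the highest numbers were 3 in carcinomas, with p of 0.157, and 2 in lymphomas, with p of 0.963. Recurrence beyond these regions was thus not detectable by this count, which takes no account of how much sequence is shared. The losses of chromosome 12 and of the rest of chromosome 4 in 3 carcinomas remained in it.

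No gene list was called detectably more often than other genes. Across 9 lists and both tumour types, one-sided permutation p-values adjusted over 18 tests lay between 0.948 and 0.994. Of the renal carcinoma genes, 15 of 80 pairs of gene and carcinoma were called, all of them losses, against 9.94 expected from the shifts, with a permutation p of 0.0991. With each tumour shifted on its own, that p was 0.0403, and its adjusted p was 0.481. The 5 members concerned were Cdkn2a, Arid1a, Mtor, Sdhb and Hif1a, each in 3 carcinomas, and 4 of the 20 measured members were lower in carcinomas by limma, both over all genes and adjusted over the list alone. Of these, Mtor, the growth kinase, was lower by -0.35 with an adjusted p of 0.0288 over all genes. Sdhb, a subunit of succinate dehydrogenase, did not pass, with an adjusted p of 0.144.

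The repair lists lay on both sides of their expected counts in carcinomas. The base excision list, which holds Mutyh, had 3 of 72 pairs called in carcinomas, against 8.97 expected with a permutation p of 0.994, and 2 of 18 members passed limma between tumour types over all genes and 3 adjusted over the list alone. The members passing over all genes were Mutyh and Parp2, lower by -0.55 and -0.40, and Pcna was added at -0.22. Parp2 and Pcna rest on 1 probe each and lay in 0 called losses. Mutyh counted as lost in 1 carcinoma and in 0 lymphomas, although its deleted probe read -2.99 ± 0.17 in the 3 knockout carcinomas. The deletion was seen at 1 Mutyh probe and a call needs at least 5 probes, so the count of this list leaves it out. In the mismatch, strand break and crosslink list, 14 of 80 pairs were called in carcinomas, against 9.97 expected with a permutation p of 0.108, and 2 of 20 members passed both ways. At a threshold of 0.4 its p was 0.0489 and its adjusted p 0.552. These were Nbn, of the double-strand break sensor complex, at -0.63 ± 0.08, and Xpa, of nucleotide excision repair, at -0.60 ± 0.07. Msh3 and Xrcc4, on chromosome 13, were in losses of KO1097 and WT1179, at -0.63 and -0.72 for Msh3 and at -0.65 and -0.72 for Xrcc4.

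The lists of iron and oxidant handling did not pass. In carcinomas 8 of 56 pairs of the iron list were called, against 6.99 expected with a permutation p of 0.421, with losses of Aco1, which encodes iron regulatory protein, in 3 tumours, and 1 of 14 members passed both ways, Aco1 at -0.51 ± 0.08. Tmprss6, a protease that limits hepcidin, was gained in WT1179 at 0.57. In the antioxidant list 4 of 56 pairs were called, against 6.98 expected with a permutation p of 0.766, and 1 of 14 members passed both ways, the peroxiredoxin Prdx1 at -0.57 ± 0.11.

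Of the cell cycle list, 12 of 76 pairs were called in carcinomas, against 9.45 expected. Its members Cdkn2a, Cdkn2c at -0.40 and Cdkn1a at -0.44, all inhibitors of cyclin-dependent kinases, were lower by limma, 3 of 19 both ways. Cdkn2c and Cdkn1a rest on 1 probe each. Cdkn2a and Cdkn2c lay in called losses of chromosome 4, whereas Cdkn1a, on chromosome 17, lay in 0 called losses. The lymphoma list had 18 of 108 pairs called in carcinomas, against 13.5 expected, and 4 of 27 members passed both ways, Pax5, Cdkn2a, Nfkbia and Bcl11b, at -0.53, -0.44, -0.59 and -0.41. In the kinase list 8 of 84 pairs were called, against 10.5 expected, and 1 of 21 members passed both ways, Akt1 at -0.62. The fragile site list had 3 of 36 pairs called, against 4.45 expected, all in Immp2l at -0.54 ± 0.08, the 1 of 9 members that passed both ways.

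In lymphomas, list genes lay mainly in gains, as did called sequence in general, with 3.26% of autosomal sequence gained and 0.217% lost. Rel, an NF-kB subunit, lay in gains of KO1111 and KO1414 and read 0.32 and 0.38, and Mpg, a DNA glycosylase for alkylated bases, read 0.54 and 0.50 there. Palb2, Dlg2 and Igf1r lay in the chromosome 7 gain of WT1113 and WT1114, and Igf1r read 0.32 and 0.24. The chromosome 6 gain of WT1405 held, among others, Braf, Met, Ezh2, Ccnd2, Vhl and Ogg1, of which Ogg1, the glycosylase for oxidised guanine, read 0.62. Called pairs in lymphomas numbered 4 of 160 for the renal, 7 of 216 for the lymphoma, 6 of 144 for the base excision and 3 of 112 for the iron list. They numbered 4 of 112 for the antioxidant, 2 of 152 for the cell cycle and 8 of 168 for the kinase list. For the mismatch and strand break list and the fragile site list they numbered 3 of 160 and 3 of 72. The expected counts from the shifts were, in the same order, 5.43, 7.29, 4.89, 3.82, 3.81, 5.16, 5.69, 5.39 and 2.41.

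Between genotypes, only Mutyh passed among the list members, over all genes and adjusted over the list alone. Between treatments, 0 list members passed over all genes by limma, which had 2329 genes at an unadjusted p under 0.05. Adjusted over the list alone, 3 passed, Hamp, the gene of the iron hormone hepcidin, at 0.37, Parp2 at 0.50 and Vegfa at -0.28. Hamp and Parp2 rest on 1 probe each, and none of these 3 genes lay in a called segment of any tumour. All untreated lymphomas lay on slide 3 and slide 2 held only treated ones, so treatment and slide overlap.

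Chromosome X had a mean log2 ratio of 0.03 ± 0.03 (SD, n = 4) in carcinomas and 0.02 ± 0.06 (n = 8) in lymphomas. Chromosome Y read -0.72 ± 0.83 in carcinomas and -0.27 ± 0.34 in lymphomas. It read -1.91 in carcinoma WT1179, where Kdm5d, Uty, Usp9y, Eif2s3y and Zfy2 read -2.30, -2.08, -2.06, -2.52 and -1.69. It read -0.49 in KO1097, -0.50 in KO1134 and 0.01 in KO1080, and among lymphomas -0.94 in WT1405, -0.54 in KO1414 and -0.45 in KO1111. Against the treated lymphomas, carcinomas differed by -0.60 on chromosome Y, with an exact permutation p of 0.119 and an adjusted p of 0.445, and by 0.00 on chromosome X, with 0.952 and 0.992. The labels give no sex for the reference animal. Against a female reference, tumours of males would read well below 0 on chromosome X. In the treated mice, which were male, it read 0.03 ± 0.03 in carcinomas and 0.03 ± 0.07 in lymphomas (n = 5). These values argue against a female reference for these tumours.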

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

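The interaction terms were chosen after the data were seen. A tumour was singled out where its distance from the nearest other tumour of its group, relative to the range of that group, passed Dixon's critical value. Of 36 groups of values tested, 6 had such a tumour, against about 1 in 20 by chance. The antigen receptor locus Igl on chromosome 16 read -0.61 in carcinoma KO1097, against a median of -0.03 in the 4 carcinomas, and it lies inside a called loss of this tumour from 11964287 to 22589504 at -0.61. The same locus read 0.14 in the treated lymphoma KO1111, against a median of 0.05 in the 5 treated lymphomas. Chromosome Y read -0.45 in lymphoma KO1111, against a median of -0.05 in the treated lymphomas. Chromosome 12 had a mean of 0.15 in lymphoma KO1414, against a median of 0.01 in the 8 lymphomas. Igk read 0.35 and Tcrb read 0.39 in lymphoma WT1405, against medians of -0.26 and -0.19 in the 8 lymphomas, and both loci lie on chromosome 6, which was gained in this tumour.

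The difference between knockout and wild type itself differed between carcinomas and treated lymphomas for 769 genes, by the interaction term of limma over 12 tumours, against 2470 genes with an unadjusted p under 0.05. Of these genes, 523 lay on chromosome 5 and 226 on chromosome 15. The wild-type side of the carcinomas is the single tumour WT1179, which carried its changes on both chromosomes, and it was assumed to vary like the other groups. Between treatments, the difference between genotypes differed for 0 genes by the same limma fit, against 662 with an unadjusted p under 0.05, and the untreated knockout side is the single tumour KO1414, likewise assumed to vary like the other groups.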

How the results depend on the processing

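Alternatives that were chosen after seeing the data are the correction for probe GC content, leaving out the regions set apart (receptor loci, the chromosome 14 interval and the sequence around Mutyh), joined neighbouring calls, WT1113 and WT1114 counted as 1 tumour, subtraction of the chromosome mean at receptor loci, recurrence centred on the mode, and gene lists with each tumour shifted on its own. The loss at Mutyh kept its direction and its exact permutation call in all 18 alternatives. The percentage called, knockouts against wild types, kept its direction without a call in all 29, between -7.01 and -3.83 percentage points. Centred on the mode, that direction came from the lymphomas, since knockout carcinomas had 21.97% and carcinoma WT1179 had 21.13%. Between carcinomas and treated lymphomas, percentages differed by 11.8 in 1 Mb bins, 17.1 centred on the mode and 11.2 with normexp, each now past the threshold, with adjusted p-values over 25 alternatives from 0.0476 to 0.333. Numbers of segments differed by 17.8 centred on the mode and 11.6 with a penalty of 20, again past the threshold, with adjusted p-values over 26 alternatives from 0.0476 to 0.848. Between treated and untreated lymphomas, the percentage turned to -3.11 centred on the mode, -4.09 at a threshold of 0.15 and -1.67 at a threshold of 0.4, and the number of segments did not change its direction or its call. The difference in segments between knockouts and wild types, 0.381, turned to -5.38 with at least 10 probes, -0.43 with calls joined, -15.7 with a penalty of 5 and -0.62 with probes well above background. It turned to -21.4 with probes centred on their median over arrays, the only alternative with a call (adjusted p of 0.0268, within a range up to 1.0 over 30 alternatives), to -8.71 without chromosome 4 and to -10.4 without the regions set apart. Leaving out single tumours gave -1.34 to 6.67. Without chromosome 4 or the regions set apart, the short losses around Mutyh no longer count, and the cause of the other shifts was not tested.

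Called genes between tumour types numbered 1021 when genes needed at least 3 probes, with 9085 genes tested. Between genotypes they numbered 7 with at least 3 probes, 8 with segment means, 0 without chromosome 4 and 0 without the regions set apart, where limma had 1005 and 1034 genes with an unadjusted p under 0.05. Between treatments they numbered 3 with means of the 6 groups, 3 with only the lymphomas, 4 with slide as a block, and 0 to 460 when single tumours were left out, with 460 without WT1121, 5 without carcinoma WT1179 and 1 without WT1420. Receptor loci that passed numbered 0 centred on the mode, 5 with the chromosome mean subtracted, and 0 to 4 when single tumours were left out, with 0 without WT1121 or WT1420, 4 without WT1405 and 2 without carcinoma KO1134. With the chromosome mean subtracted, Igh turned to -0.31 and Tcrg to -0.066, and Tcrg ranged from -0.051, without carcinoma KO1097, to 0.15 when single tumours were left out. Recurrence in carcinomas no longer passed centred on the mode (4 tumours), at a threshold of 0.15 (4), with probes centred on their median (3), or without the regions set apart (3). Leaving out single carcinomas gave 3 to 3 tumours, which passed except without KO1134, where p was 0.209. In lymphomas it no longer passed without the regions set apart (2). At thresholds of 0.15 and 0.4 and with separate shifts, 0 gene lists passed the permutation test. Correction for GC content with a genome sequence was not run. No paired analysis was possible because the groups share no replicate numbers. Probes not well above background on all arrays numbered 360, and without them limma called 2529 genes between tumour types, 12 between genotypes and 0 between treatments.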

Other observations

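The tests of strain sequence beside Mutyh, of both explanations for carcinoma KO1134, of shared DNA and of slide for lymphomas WT1113 and WT1114, and the counts of splits were chosen after the result was seen. The tests of deletion during tumour growth and of a common founder cell were set before their values were computed.

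Centred on the mode, carcinoma KO1134 held losses at similar levels on chromosomes 3, 4, 8, 9, 10, 12, 13 and 14. Chromosome 8 lay at -0.29 up to 124319367, chromosome 10 at -0.29 from 5600264, chromosome 12 at -0.30 up to 88912636, and chromosome 9 at -0.29 from 49333181 to its end. Chromosome 4 lay at -0.30 by its median, so that this chromosome and the first part of chromosome 12 were low in all 4 carcinomas. If these losses are 1 copy of a diploid genome, the share of cells with the loss of chromosome 4 was 51.7% in KO1080, 74.9% in KO1097, 37.5% in KO1134 and 80.3% in WT1179. For chromosome 12 the shares were 51.1%, 72.2%, 38.0% and 80.1%, and for chromosome Y 0.9%, 31.4%, 32.2% and 77.1%. Lymphoma WT1405, centred the same way, had gains over all of chromosome 11 at 0.28, chromosome 15 at 0.29, chromosome 17 between 0.27 and 0.28, and chromosome 6 between 0.50 and 0.53.

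The gain on chromosome 14 from 69876584 to 70090608 covered 23 probes and the genes Slc25a37, the mitochondrial iron importer mitoferrin, Entpd4 and Loxl2. It lay between 0.68 and 0.94 in 10 tumours, of both types and both genotypes, and at 0.03 in lymphomas WT1113 and WT1114. These genes were chosen after their values were seen, and no explanation was tested.

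The losses beside Mutyh lay in each knockout tumour at the same probes. Deletion during tumour growth would give a depth that follows the share of tumour cells, yet the SD of the depth over the 6 knockouts was 0.185 around a mean of -3.11, while that share lay between 37.5% and 74.9% in the 3 knockout carcinomas, which argues against it. The depth, taken below the chromosome 4 mean, was -3.44 in KO1134, the carcinoma with the lowest share, -2.91 in KO1097 and -2.98 in KO1080. Without that subtraction, these probes read -3.70, -3.56 and -3.41 in the same tumours. Sequence of another strain carried along with the knockout allele remains a candidate explanation, since 100% of the probes lay on chromosome 4 within 20 Mb of Mutyh. Whether these probes read a deletion in that strain or a difference in its sequence stays open, and an effect of the Skint genes was not tested.

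Carcinoma KO1134 had only 1.29% of its autosomal sequence called. Centred on the mode, 35.3% was called, so that the low percentage may come from centring on the median in a genome with many losses. A lower share of tumour cells cannot be told apart from a higher number of genome copies, since both give a shallow level, here -0.30 for chromosome 4 against -0.43, -0.68 and -0.74 in the other carcinomas. At that share, the focal gains on chromosomes 3 and 9 come to 3.06 and 2.89 extra copies. No biological explanation was tested.

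Lymphomas WT1113 and WT1114, of different animals by their labels, had profiles that correlated at 0.743 over 1 Mb bins, against at most 0.431 for the other 27 pairs of lymphomas, and shared 2 break points. The same DNA in both samples would keep the ratio of the chromosome 15 gain to the chromosome 7 gain alike, but it differed by 0.778. Partial carry-over of 1 DNA into the other sample need not keep that ratio, so this test cannot decide on it. Over chromosome 1 from 66162753 to 197188537, WT1114 read 0.31 and WT1113 read 0.18. The slide is argued against by the chromosome 7 interval, which was at most 0.017 on the other 2 arrays of the same slide. A common founder cell is consistent with the correlation over Igh probes of 0.91, against at most 0.833 in other pairs. How 1 founder could reach 2 animals was not tested, and an error in the labels of animals or a descent of both from 1 line stays open, with the chromosome 14 interval at 0.03 in both against 0.68 to 0.94 in the other 10 tumours.

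For the genes that differ between tumour types, 1 of 100 splits of the tumours, the real one, called 2536 genes or more, and the highest other split called 347. No other split that was drawn thus came near the real count, but only a part of the possible splits was drawn. All 4 carcinomas lay on slide 1, so this count cannot tell tumour type from slide. For genotypes, 3 of 100 splits, the real one included, called at least 13 genes. Arbitrary splits thus reached that count too, so it does not exclude chance. Without chromosome 4 limma called 0 genes between genotypes, against 1005 with an unadjusted p under 0.05. The real count therefore rests mainly on the sequence around Mutyh. The highest other split called 705, with all 4 carcinomas and lymphomas WT1113 and WT1114 on 1 side, which points to a structure of the samples. Beside the term for tumour type, this split sets WT1113 and WT1114 against the other lymphomas, and the source of its calls was not tested. Between treatments, the real split called 0 genes by limma, against 2329 with an unadjusted p under 0.05. All 56 splits reach 0 by construction, so this count says nothing about chance. The highest other split called 822, with all 5 wild-type lymphomas on 1 side, which points to a structure of the samples. Beside the term for genotype, that split takes the genotype difference from the carcinomas, where WT1179 is the lone wild type, and the source of its calls was not tested.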
